A study of Homo sapiens with 6 samples.

How the data were processed

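Messenger RNA was profiled in 6 libraries of PANC-1, an established human pancreatic carcinoma cell line. The labels put 3 libraries in a group given 50 µM D(+)-raffinose pentahydrate for 24 h and 3 in a group with no compound named. Raffinose is a plant trisaccharide that contains galactose. For the untreated group the labels of the single libraries name neither a vehicle nor a time. Nothing in the labels says that the libraries of a group came from separate cultures, so every p-value measures the spread between these libraries, which may be technical.

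Per the labels' protocols, poly(A) RNA was fragmented and copied into strand-marked libraries with dUTP in the second strand, and sequenced as read pairs of 150 bases on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 without saying what each was used for. The genome build and annotation are not given in the sources used here. Of the gene identifiers in the table, 58394 also occur in GENCODE 29, where 84.6% have the same start position. Coordinates below are those of the deposited table. Whether the counting used the strand is also not given in the sources used here.

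The authors deposited one table of 60612 genes with an FPKM value and an estimated count for each library, per the file headers. In the deposited FPKM columns a gene with no reads is listed at 0.0001. The deposited estimated counts are whole numbers, and values of 4 and 8 are far more frequent than their neighbours. In raffinose replicate 1, for example, 1382 genes had a count of 4, 456 a count of 3 and 286 a count of 5. One read pair therefore seems to add 4 to the value, so the counts overstate the number of fragments. The total count was 63357047, 63553897 and 62756117 in raffinose replicates 1, 2 and 3, and 66063664, 64387041 and 59723420 in untreated replicates 1, 2 and 3.

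The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 18863 genes, libraries were scaled by TMM, and the groups were compared with glmQLFit and glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Before the data were examined, the design named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR for a table with counts. As counts were present, edgeR became the main test and the FPKM fit an alternative. Levels are given as CPM (counts scaled to library size) after TMM scaling, as mean ± SD over 3 libraries, and fold changes as log2 of raffinose over untreated with the standard error (SE) of the edgeR fit.

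Altogether 35 gene lists were fixed before the data were examined. They cover the pathways in the series title, stress, growth and metabolism, and markers of other cell types. Of their 959 entries, 938 matched a gene of the table. The 32 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on the count data with a preset correlation of 0.01, in place of the FPKM matrix named in the design, and adjusted by Benjamini-Hochberg over the lists. Each was also tested with an estimated correlation and with fry. GO and KEGG terms paired with genes in the table were tested with a one-sided hypergeometric test for terms of 10 to 500 tested genes.

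Named genes followed a rule fixed before the data were examined. It takes the 10 largest changes per direction among called genes with a mean FPKM of at least 1 in a group and groups that do not overlap, up to 4 members with the smallest p of each list described, and, whatever their values, genes fixed from the series title and the compound, among them AKT1, AKT2, PIK3CA, BCL2, BAX, CASP9, CCND1, CDKN1A, MKI67 and GLA. Some genes that the rule takes are not reported here. Any other gene named below was chosen after its values were seen.

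The fits were tested on simulated counts with 200 changed genes drawn from the means and library sizes of the raffinose and untreated comparison, over 18863 genes. edgeR recovered 6% of changes of 1.5-fold, 48% of 2-fold, 72% of 4-fold and 74% of 8-fold, with 8 false calls. DESeq2 1.42.0 recovered 20% of changes of 1.5-fold, 60% of 2-fold, 80% of 4-fold and 82% of 8-fold, with 71 false calls. A simulated list shifted by 1.5-fold was called, and 0 of 50 lists without a shift were called by camera. The simulated genes were independent of each other, so this cannot show how often camera calls lists of correlated genes. The common biological coefficient of variation in the real libraries was 27.1%.

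Alternatives were limma on log2(FPKM + 0.1) and log2(FPKM + 0.01), no filter, a filter at FPKM 5, quantile normalization, median ratio scaling, limma without an intensity trend or with sample weights, the replicate number as a block, a 1.5-fold threshold, DESeq2, DESeq2 size factors, and each library left out in turn. After seeing the data, limma on log2(FPKM + 1), edgeR with a filter at FPKM 1, counts divided by 4, and edgeR with robust dispersion were added. No 2 libraries agreed within sampling noise, so all 6 were counted.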

Results

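Poly(A) RNA of PANC-1 cells was sequenced in 3 libraries after 24 h with 50 µM raffinose pentahydrate and in 3 untreated libraries. The total count per library ranged from 59723420 to 66063664, in units that overstate fragments. The series title names the PI3K/AKT pathway, apoptosis and proliferation as what the comparison addresses.

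In raffinose-treated cells 7 genes rose and 16 fell among 18863 tested. HACD3, a dehydratase of the fatty acid elongation cycle, fell from 205 ± 8.27 to 69.2 ± 2.18 CPM, and RFX7, a transcription factor of the RFX family, fell from 41.9 ± 7.22 to 4.15 ± 0.632 CPM (SD, n = 3 per group). EGR1, an immediate early transcription factor, rose from 5.42 ± 0.204 to 16.8 ± 0.214 CPM. The endoplasmic reticulum chaperone CANX rose from 818 ± 55.5 to 1430 ± 61.0 CPM. The groups did not overlap for any of the 23 called genes.

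By edgeR with Benjamini-Hochberg adjustment, RFX7 (ENSG00000181827, chromosome 15, 56087280 to 56245082, minus strand) had a log2 fold change of -3.34 (SE 0.18, adjusted p = 0.00537). HACD3 (ENSG00000074696, chromosome 15, 65530418 to 65578349, plus strand) had one of -1.57 (SE 0.06, adjusted p = 0.00131). EGR1 (ENSG00000120738, chromosome 5, 138465479 to 138469303, plus strand) had one of 1.63 (SE 0.09, adjusted p = 0.00537). CANX (ENSG00000127022, chromosome 5, 179678628 to 179730925, plus strand) had one of 0.81 (SE 0.07, adjusted p = 0.0171).

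Other genes that rose were SLC39A9, a zinc transporter, with a log2 fold change of 1.505, the membrane protein gene TMEM123 with 1.43, the dehydrogenase DHRS2 with 1.42, SYDE1 with 0.99, and CCN2, a matricellular growth factor, with 0.69. SLC39A9 overlaps ERH on the opposite strand, whose level was lower by 14.4 CPM while that of SLC39A9 was higher by 23.9 CPM. Among genes that fell, the glycine transporter SLC6A9 had a log2 fold change of -0.93 and IGFBP4, which binds insulin-like growth factors, one of -0.89. DLST, a subunit of the alpha-ketoglutarate dehydrogenase complex, had -0.85 and the kinetochore gene KNSTRN -0.84. The stathmin STMN3 had -0.74, the MAP kinase phosphatase DUSP4 -0.71 and the peptidylarginine deiminase PADI2 -0.64. A further 6 called genes also fell: COL13A1 (-1.36), SH2D5 (-0.62), ETS2 (-0.62), ANPEP (-0.60), TGM2 (-0.49) and CDCP1 (-0.47). Of these lower genes, 9 were called in none of the 6 fits that left out a library. They were SLC6A9, STMN3, DUSP4, PADI2, COL13A1, SH2D5, ETS2, TGM2 and CDCP1.

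**Figure D1:**
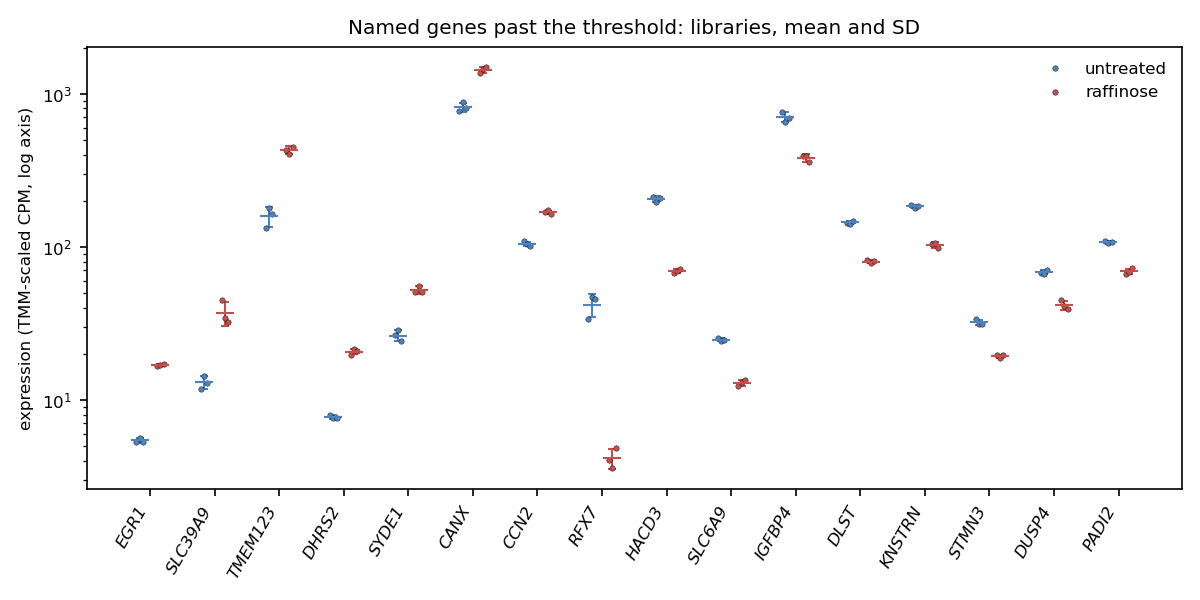
TMM-scaled CPM on a log axis for 16 called genes that the rule names, in the 3 untreated (blue) and 3 raffinose (red) libraries, as points with the mean and SD. RFX7 lies near 4.15 CPM with raffinose and 41.9 CPM without. The groups do not overlap for any gene drawn, which the rule requires.

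Of all tested genes, 2506 had an unadjusted p under 0.05 where chance gives 943, and 21.5% had groups that did not overlap where chance gives 10%. DESeq2 called 254 genes higher and 409 lower, including all 23 edgeR calls in the same direction. On simulated counts DESeq2 made 71 false calls and edgeR 8, so some DESeq2 calls here and below may be false. Without untreated replicate 3 edgeR called 0 higher and 4 lower, with 1969 genes at an unadjusted p under 0.05. RFX7 and HACD3 were the 2 genes called in all 6 fits that left out a library.

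For the pathway in the title, none of the genes named here passed the test. AKT1 was at 129 ± 7.65 CPM without and 118 ± 8.22 CPM with raffinose (log2 fold change -0.13, SE 0.08), and AKT2 at 1134 ± 41.6 and 1035 ± 41.2 CPM (-0.13, SE 0.05). The kinase subunit PIK3CA was at 21.2 ± 3.44 and 26.9 ± 3.00 CPM. Their edgeR adjusted p ranged from 0.358 for AKT2 to 0.542 for AKT1. GLA, the lysosomal alpha-galactosidase, was at 68.6 ± 9.58 and 67.5 ± 6.20 CPM.

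Among the 37 tested PI3K/AKT pathway components, 18 had a positive and 19 a negative log2 fold change, and 0 passed by edgeR over all genes, while DESeq2 called 3 higher and 2 lower. Adjusted over the list alone, 3 rose and 2 fell. The regulatory subunit gene PIK3R3 (log2 fold change 0.39) and the transcription factors FOXO1 (1.03) and FOXO4 (0.62) rose, while MLST8 (-0.42) and RPTOR (-0.26), subunits of mTOR complexes, fell. As a set the list was not called by camera (adjusted p = 0.421), and its median of -0.01 differed in sign from its mean of 0.10 and from the test.

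FOXO target genes, which FOXO factors can activate when AKT is less active, rose as a set, with 19 of 24 tested members positive and a median log2 fold change of 0.27 (camera adjusted p = 0.00115). With an estimated correlation the call was lost (adjusted p = 0.204). No member passed over all genes or adjusted over the list alone by edgeR. DESeq2 called 2 of them higher. KLHL24 had a log2 fold change of 0.68 (SE 0.14), GADD45A 0.26 (SE 0.07), BCL2L11 1.22 (SE 0.31) and SESN3 1.29 (SE 0.36).

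Apoptosis genes did not pass as sets. Among 32 pro-apoptotic genes 22 were positive (camera adjusted p = 0.112). Adjusted over the list alone BMF, a BH3-only gene, rose from 9.13 ± 0.332 to 15.4 ± 0.898 CPM and the death receptor TNFRSF1A fell from 114 ± 14.2 to 80.4 ± 5.62 CPM. BAX was at 56.6 ± 5.35 CPM without and 50.1 ± 0.603 CPM with raffinose, and CASP9 at 10.7 ± 2.78 and 14.8 ± 3.92 CPM. Of 17 anti-apoptotic genes, BIRC2 rose and BAG3 fell adjusted over the list alone, and the list had an adjusted p of 0.997. BCL2 was at 5.83 ± 2.17 and 8.14 ± 0.226 CPM. The p53 target list had a median of 0.18 and an adjusted p of 0.081, with RRM2B, TP53INP1, CCNG1 and SESN2 higher and AEN and DDB2 lower adjusted over the list alone.

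**Figure D2:**
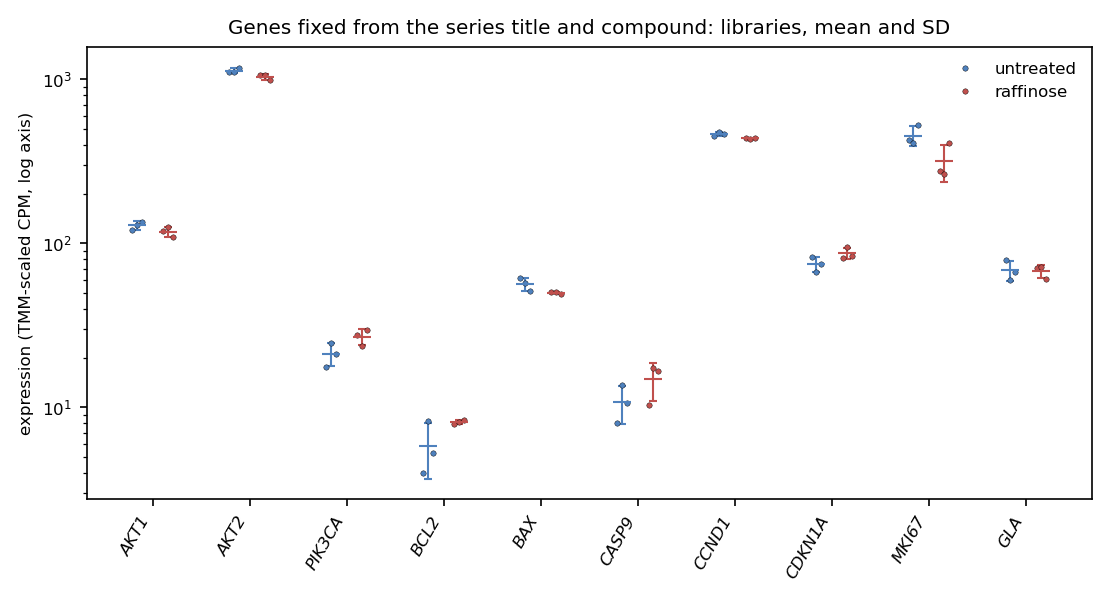
TMM-scaled CPM on a log axis for 10 genes fixed from the series title and the compound, in the 3 untreated (blue) and 3 raffinose (red) libraries, as points with the mean and SD. None of the genes drawn passed the edgeR test, and CASP9 was at 10.7 ± 2.78 CPM without and 14.8 ± 3.92 CPM with raffinose.

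G1/S and DNA replication genes fell as a set, with 33 of 45 members negative and a median log2 fold change of -0.08 (camera adjusted p = 0.00309; adjusted p = 0.204 with an estimated correlation). Adjusted over the list alone the replicative helicase genes MCM5 (-0.36) and MCM7 (-0.28) fell. CCND2 had a log2 fold change of 1.09 (SE 0.27) from 1.19 ± 0.334 CPM and did not pass. CCND1 was at 464 ± 11.7 CPM without and 438 ± 4.51 CPM with raffinose. G2/M and mitosis genes had 24 positive and 20 negative members and an adjusted p of 0.743, and their median of 0.01 differed in sign from their mean of -0.02 and from the test. The proliferation marker MKI67 was at 455 ± 63.7 and 317 ± 80.6 CPM (log2 fold change -0.52, SE 0.19, edgeR adjusted p = 0.319). CDK inhibitors had an adjusted p of 0.128, and CDKN1A was at 74.9 ± 7.98 and 87.0 ± 7.08 CPM. Replication-dependent histone genes had a median of 0.29 and an adjusted p of 0.112.

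MYC target and ribosome biogenesis genes fell as a set, with 40 of 44 members negative and a median log2 fold change of -0.18 (camera adjusted p = 9.8e-09; adjusted p = 0.204 with an estimated correlation). By edgeR 0 members passed over all genes and 11 fell adjusted over the list alone, and DESeq2 called 7 lower. The ribosome assembly genes RRS1 (-0.43, SE 0.06), MRTO4 (-0.32, SE 0.06) and PES1 (-0.30, SE 0.06) and the nucleolar factor TCOF1 (-0.35, SE 0.07) were among them. MYC itself, named after its values were seen, was at 11.4, 65.7 and 61.3 CPM in raffinose replicates 1, 2 and 3 and at 8.0 to 13.1 CPM in untreated libraries, and did not pass. Cytosolic ribosomal proteins had 36 of 48 members negative, a median of -0.07 and an adjusted p of 0.0904.

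ATF4 and amino acid response genes fell as a set, with 25 of 33 members negative and a median of -0.19 (camera adjusted p = 4.6e-04; adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone 13 fell and 4 rose, and 0 passed over all genes by edgeR, while DESeq2 called 3 higher and 6 lower. CBS, an enzyme of cysteine synthesis, had a log2 fold change of -0.45 (SE 0.06), the secreted glycoprotein STC2 -0.38 (SE 0.05), the amino acid transporter SLC7A5 -0.30 (SE 0.04) and the serine synthesis enzyme PSAT1 -0.31 (SE 0.06). The stress-induced genes ATF3, DDIT4 and SESN2 and the transporter SLC38A2 were the 4 that rose.

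Epithelial genes fell as a set, with 11 of 17 members negative and a median of -0.16 (camera adjusted p = 0.00761; adjusted p = 0.204 with an estimated correlation). The simple-epithelium keratin KRT18 fell from 1944 ± 153 to 1416 ± 100.4 CPM and KRT8 from 3291 ± 434 to 2240 ± 245 CPM, and CLDN1, CLDN7 and KRT7 also fell, all adjusted over the list alone. CDH1, the adherens junction cadherin, was at 75.8 ± 7.57 and 68.3 ± 3.17 CPM. Without untreated replicate 1 the adjusted p of this list was 0.0506. Mesenchymal and EMT genes were not called as a set (adjusted p = 0.516). Adjusted over the list alone 5 of them rose and 4 fell. CCN2 was among those that rose, and the urokinase PLAU (-0.56) and the matrix gene TNC (-0.97) among those that fell.

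Mitochondrially encoded genes rose as a set, with 14 of 15 positive and a median of 0.08 (camera adjusted p = 0.0417; adjusted p = 0.649 with an estimated correlation). MT-RNR2 (0.28) and MT-ND4L (0.15) rose adjusted over the list alone. The call was lost without raffinose replicate 1 or 2 or untreated replicate 2 or 3 (adjusted p from 0.114 to 0.278). Reads of the mitochondrial chromosome made up 9.35% to 9.66% of counts in raffinose libraries and 8.47% to 9.54% in untreated ones. Nuclear oxidative phosphorylation genes had a median of -0.03 and an adjusted p of 0.112.

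The remaining lists were not called by camera. The adjusted p was 0.0904 for hypoxia targets, 0.112 for heat shock genes, 0.112 for NF-kB and inflammatory genes, 0.224 for lysosome and autophagy genes, 0.272 for NRF2 targets, 0.298 for galactose metabolism, 0.310 for glycolysis and 0.310 for the ER chaperone list that holds CANX. It was 0.335 for fatty acid synthesis, 0.421 for interferon-stimulated genes, 0.421 for YAP/TEAD targets, 0.516 for ERK/MAPK response genes and 0.790 for cholesterol synthesis. In the ERK/MAPK list EGR1 rose and DUSP4 fell over all genes, and adjusted over the list alone FOS also rose (0.82) and SPRY2 fell (-0.32). In the hypoxia list P4HA1 (0.37), KDM3A (0.34), BHLHE40 (0.27) and NDRG1 (0.41) rose adjusted over the list alone. In the glycolysis list SLC2A3 (0.54) and ENO2 (0.70) did so, and in the YAP/TEAD list CCN2, ANKRD1 (0.47), GADD45A (0.26) and CCN1 (0.38) rose and FJX1 (-0.40) fell. For the NRF2, cholesterol and endocrine lists the median and mean differed in sign, and for the anti-apoptotic list the test differed from both.

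**Figure D3:**
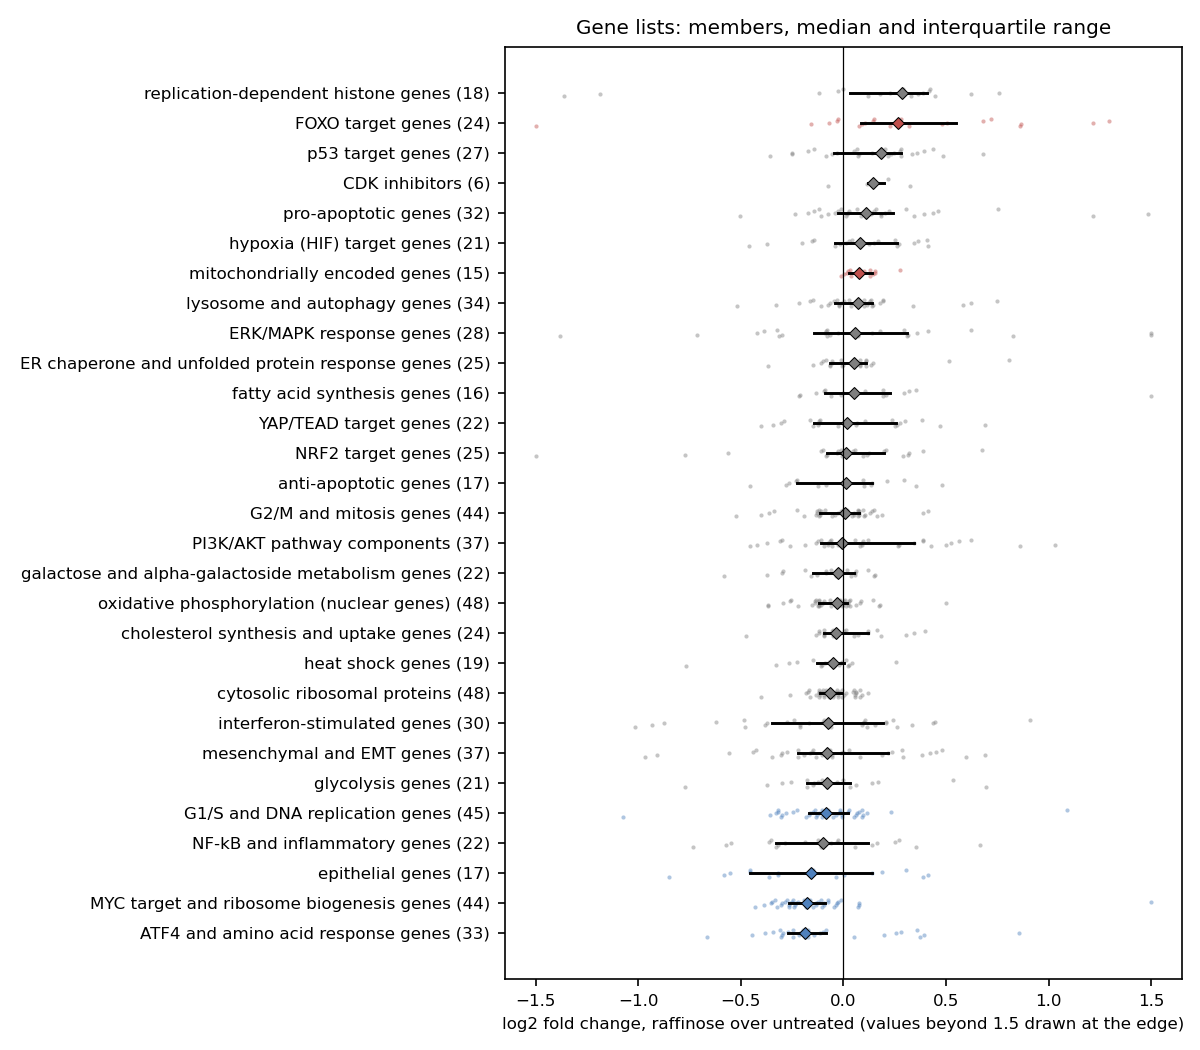
Log2 fold changes, raffinose over untreated, of tested members (small points), with the median (diamond) and interquartile range (bar), for 29 gene lists with the number of tested members in brackets. Lists called lower by camera are blue and those called higher are red. FOXO targets have a median of 0.27 and ribosome biogenesis genes one of -0.18, and both calls were lost with an estimated correlation.

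Lists of markers of other cell types were not called by camera, with an adjusted p of 0.743 for fibroblast markers, 0.677 for leukocyte markers and 0.790 for pancreatic endocrine markers. Of the fibroblast markers, the collagen gene COL3A1 fell from 386 ± 10.8 to 331 ± 9.23 CPM, and of the endocrine markers the secretogranin SCG2 fell from 5.79 ± 0.486 to 3.95 ± 0.435 CPM, both adjusted over the list alone. A mean FPKM of at least 1 was reached by 4 fibroblast, 4 endocrine and 1 leukocyte markers. Of the endothelial, erythroid and acinar markers 2, 1 and 1 genes were expressed enough to be tested, and these lists were not tested as sets. No GO or KEGG term was enriched among the edgeR calls, with 0 of 3798 terms past the adjusted threshold and 170 at an unadjusted p under 0.05.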

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

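The alternatives added after seeing the data were limma on log2(FPKM + 1), edgeR with a filter at FPKM 1, counts divided by 4 and edgeR with robust dispersion. Against 7 genes higher and 16 lower, limma called 18 and 28 on log2(FPKM + 0.1), 18 and 25 on log2(FPKM + 0.01), 17 and 27 on log2(FPKM + 1), 29 and 50 after quantile normalization, and 92 and 138 with sample weights. DESeq2 called 254 and 409, and all 23 edgeR calls were among them. On simulated counts DESeq2 made 71 false calls and edgeR 8, so some of the further DESeq2 calls may be false. The edgeR filter at FPKM 5 gave 30 and 78 among 6413 genes tested, and that at FPKM 1 gave 15 and 28 among 11809. Counts divided by 4 gave 11 and 24. The cause of the differences between these settings was not tested. With each library left out in turn, genes higher ranged from 0 to 15 and genes lower from 4 to 13. More genes rose than fell without untreated replicate 1 (15 higher, 8 lower) and without untreated replicate 2 (12 higher, 8 lower). The 0 came without untreated replicate 3, where 1969 genes had an unadjusted p under 0.05 in edgeR. The limma sample weights were highest for that library (2.07) and lowest for untreated replicate 1 (0.471). Without raffinose replicate 1, which had a weight of 2.02, edgeR called 6 higher and 12 lower. Fewer samples remain in all 6 fits that left out a library, which does not set any of them apart. Of the 23 calls, 2 were made in all 6 of these fits, 9 in at least 3 and 9 in none.

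The replicate number as a block gave 0 genes higher and 0 lower in edgeR, with 1932 at an unadjusted p under 0.05, and 6 lists. On simulated counts without any effect of the replicate number, edgeR recovered 28% of changes of 2-fold with the block and 48% without it. The loss of calls therefore does not by itself speak for pairing. Deviations from the group means of libraries that share a number had correlations of -0.01, -0.03 and 0.01. Of 6 libraries, 0 correlated best with their own number, so no pairing by number was seen. The labels do not say whether libraries with the same number shared a culture or day, and these correlations cannot exclude it.

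The count of 6 lists became 11 with limma on log2(FPKM + 0.1), 11 on log2(FPKM + 0.01), 11 on log2(FPKM + 1), 11 at FPKM 5, 12 after quantile normalization, 10 with sample weights and 0 with an estimated correlation, which takes the correlation from the residuals of 6 libraries. With fry 4 lists were called. The FOXO (adjusted p = 0.0553), ATF4 (0.0553) and mitochondrially encoded (0.292) calls were lost there, and the ER chaperone list was called (0.0351). The count ranged from 5 to 10 with each library left out, 10 being without raffinose replicate 3. The ribosome biogenesis list was called in the same direction in 20 of 21 alternatives, as was the G1/S list, and the FOXO, ATF4 and epithelial lists in 19. The mitochondrially encoded list was called in 14. With genes taken at an unadjusted p under 0.01, 12 terms passed in place of 0, since more genes entered the test.

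Among the 137 genes followed, the direction of GLA turned, with log2 fold changes of 0.019 on log2(FPKM + 0.1), 0.019 on log2(FPKM + 0.01), 0.017 on log2(FPKM + 1), 0.015 at FPKM 5, 0.017 without an intensity trend, 0.0087 after quantile normalization, 0.032 with median ratio scaling and 0.065 with sample weights, and from -0.11 to 0.089 with libraries left out. It was not called.

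Lists that were never called in either direction also turned. The G2/M list had adjusted p of 0.620, 0.621 and 0.621 with limma at pseudocounts of 0.1, 0.01 and 1, 0.50 at FPKM 5, 0.961 at FPKM 1, 0.0965 after quantile normalization, 0.790 with median ratio scaling, 0.650 without an intensity trend and 0.897 with sample weights. The mesenchymal list had 0.957 at FPKM 5, 0.980 at FPKM 1, 0.979 after quantile normalization and 0.914 with sample weights, and the PI3K/AKT list 0.957 at FPKM 5 and 0.914 with sample weights. The anti-apoptotic list had 0.973 with median ratio scaling, 0.979 with the replicate block, 0.920 with counts divided by 4, 0.944 with fry, and 0.468 to 0.972 with libraries left out. The ERK/MAPK list had 0.770 at FPKM 5 and leukocyte markers 0.934 with no filter. After quantile normalization the glycolysis list had 0.987 and heat shock genes 0.944. With libraries left out leukocyte markers had 0.599 to 0.947, fibroblast markers 0.576 to 0.973, YAP/TEAD targets 0.258 to 0.952 and cholesterol genes 0.721 to 0.940. Cytosolic ribosomal proteins (0.703) and nuclear oxidative phosphorylation genes (0.440) also turned after quantile normalization, and both were called in some other alternatives. The cause was not tested. On simulated counts edgeR recovered 6% of changes of 1.5-fold, so changes of that size were mostly not detectable with these libraries.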

Other observations

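Genes at an unadjusted p under 0.01, of which 285 were higher and 464 lower with raffinose, were enriched for 12 GO or KEGG terms past an adjusted p of 0.05, all among lower genes. The hypergeometric test treats genes as independent of each other, and several of these terms hold the same genes. The ribosome biogenesis, ATF4 and epithelial lists hold some of these genes too, and their camera calls were lost with an estimated correlation. Of 43 genes of tRNA aminoacylation, which charges tRNAs with amino acids, 10 were among the lower genes (23.3% against 3.44% of all genes with a term), including AARS1, GARS1, NARS1 and KARS1. The large-subunit preribosome term held 8 of 23, with PES1, BOP1 and RRS1. The keratinization term held 8 of 32, among them KRT4 and KRT15, and focal adhesion held 31 of 377, among them PLAU, ACTN1, HACD3 and TGM2. Of the genes named here, only HACD3 and TGM2 passed the edgeR test over all genes.

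The test of amino acid depletion below was chosen only after the result was seen.

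The 23 called genes, led by HACD3 and RFX7, were weighed against causes in the counting and in the cultures. Among the 10 called genes that overlap another, opposite changes of overlapping genes offset a median of 5.1e-04 of the gene's change in CPM. For these genes this argues against reads moved between annotated overlapping genes, and SLC39A9, at 0.603, is the exception. The other called genes overlap no gene of the table, so their share is 0 by definition. The median of 0 over all 23 therefore adds nothing. The 20 nearest tested genes had a median of 0.0089 of the gene's own log2 fold change. For the called genes as a set this argues against gained or lost chromosome segments that span these neighbours. The share was highest for CCN2 (0.325), TGM2 (0.253) and ANPEP (0.223), and shorter segments would be missed. Steps in the estimates that fall on libraries at random cannot be told apart from an effect of raffinose. At a mean of 10 CPM or more, 21 genes had groups separated by a gap of at least 1.5-fold. This was 1.73 times the mean of 12.1 over the other 9 splits, with a 95% Poisson interval from 1.07 to 2.65, and the highest of them had 19. At a gap of at least 2-fold the real split had 7 genes, and the other splits had a mean of 4.89 and a highest count of 8. Steps also occur within groups, as 295 of 9884 genes at this level had a 3-fold range within a group. Reads given to transcripts outside the table may be a source of steps like that of MYC, but this was not tested.

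Ribosome biogenesis genes were lower while FOXO targets were higher with raffinose. After removal of a trend on GC content and transcript length the smaller share of either list's median that stayed was 0.928, which argues against such a trend. Among 10000 random lists matched on expression none had a median as extreme for either list (two-sided share 2e-04, the smallest these draws can give), which argues against a trend with expression level. Amino acid depletion of the treated cultures would raise ATF4 targets, but their median log2 fold change was -0.188 (95% bootstrap interval -0.217 to -0.116). The bootstrap drew genes and not libraries, so its interval leaves out the variation between libraries. The call of that list was lost with an estimated correlation (camera adjusted p = 0.415) and with fry (adjusted p = 0.0553). By edgeR adjusted over the list alone, 13 members fell and 4 rose. Amino acid depletion is therefore not excluded. An effect of raffinose, chance, and the shared variation that ends the camera calls with an estimated correlation stay open. A difference between the groups in vehicle or culture time also stays open. The labels of the untreated libraries name neither, so it cannot be told apart from an effect of raffinose.

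The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes called the real split gave 23 and the highest other split 13, so 1 of the 10 splits gave as many. For lists called the real split gave 6 and the highest other 3, and again 1 of the 10 gave as many.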
